A study of Rattus with 4 samples.

How the data were processed

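RBM25-bound RNA and input RNA of H9C2 cells were sequenced by the submitters, with 2 samples of each. Per the labels' protocols, cells were cross-linked with ultraviolet light. A DNase treatment was used, RNA was digested with micrococcal nuclease, and stranded total RNA libraries were sequenced as read pairs. HISAT2 and the rat build mRatBN7.2 are named per the submitters' processing notes; the peak caller, its filters and any use of the inputs are not given in the sources used here. The deposited peak lists, which hold 1 IP sample each by their names, give for each peak a position, strand, tags, p-value, length and annotation. The tags column is a signal, per the file headers and values: in 51-nt peaks it was whole throughout, and in longer peaks it was the mean over 50-nt bins. It was not scaled for depth, so the authors' tags were used to describe and rank peaks and not to test a change between replicates. The deposited p-value of 51-nt peaks took 1 value per tag number and strand, in all 137 such combinations of replicate 1 and all 199 of replicate 2, which leaves no room for a local input level in it. All starts lay on a 50-nt grid, so the smallest overlap that could occur was 1 bin. The inputs were not analysed here.

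Peaks were called shared when they overlapped on the same strand. Location is the annotation class that covers most of a peak in the deposited annotation. Genome sequence and gene models of the build were not used here, which changed the planned tests. The planned placement inside annotated genes became placement inside the span of the peaks of that gene in both lists. That span is narrower, which raises the expected overlap. Placement was even over it and not matched on exon or intron, which lowers the expected overlap where peaks favour exons. The planned share within 100 nt of a splice site became the share of sense peaks that hold both exon and intron sequence, a description with no random expectation. Location was also given with no expectation from random placement. Random gene lists were not matched on gene span. Motifs were not analysed here.

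Random placement used 1000 draws (one-sided), gene lists 10000 random lists of protein-coding genes (two-sided) and correlations 100000 permutations. Location and gene lists were compared by two-sided Fisher exact test, with Benjamini-Hochberg adjustment within each family: 9 comparisons between lists, 2 of boundary peaks, 8 gene lists and 7 pairs of gene lists. Peaks of a list are not independent, so these tests compare the 2 lists and not conditions. Of 1914 gene names in the lists, 1829 matched a symbol of a RefSeq name table (assembly GRCr8, used for names alone), 19 matched a synonym and 66 did not match. Ribosomal RNA loci were unplaced scaffolds and peaks within 50 kb of a peak in a nuclear ribosomal RNA gene.

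The 12 gene lists, with 473 entries, were fixed before the data were examined. Named genes followed a rule fixed at the same time: the 10 genes with the best mean rank of their strongest shared peak, up to 4 members per list by that rank, all study genes and known targets, and the 3 genes with the strongest peak in each list that have none in the other; unnamed identifiers were passed over. A gene that the rule names is not reported here. Other genes named as members of a list were chosen after their values were seen. Alternatives covered the threshold, the overlap rule, strand, placement, chromosomes, the definition of location, leaving out each replicate, the backgrounds and peak length. Shuffling over called bins, sense peaks alone for genes, and leaving out ribosomal, mitochondrial and scaffold peaks for location were added after seeing the data. The tests of recurrence by tag class, of mirrored strands, of boundary peaks by sharing, of boundary and ribosomal RNA peaks between the lists, and of pairs of gene lists were also chosen after seeing the data.

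Procedures were tested on simulated data. Over 2590 genic peaks, placement recovered 4.56% of extra sharing where 5% was planted and 28.0% where 30% was planted, and called 0 of 20 simulations with none planted. The list test called 2 of 200 lists with no extra members and 200 of 200 with 20% extra. Simulated peaks without planted sharing were placed evenly over the same spans that the test uses, and list members were drawn independently. These checks cover the computation, and not peaks that favour exons or lists of genes expressed together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.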

Results

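RNA bound by RBM25, a U1 snRNP-associated splicing factor, was profiled in H9C2 cells, a myoblast line derived from embryonic rat heart. Cells were cross-linked with ultraviolet light, and RNA that came down with RBM25 was digested with micrococcal nuclease, sequenced and summarised as peaks. The series has 4 samples, 2 RBM25 immunoprecipitates (IP) and 2 inputs, and a peak list of each IP was analysed; the inputs were not used here. Replicate 1 had 2696 peaks with a median of 24 tags per 50-nt bin, and replicate 2 had 8108 peaks with a median of 26. Most peaks were 51 nt long, 2560 in replicate 1 and 7537 in replicate 2. The lowest peak had 19 tags in replicate 1 and 20 in replicate 2, and the depth of the libraries is unknown, so the length of a list can follow depth. Intervals are 95% Wilson intervals over peaks or genes of a list and cover counting error only. Nothing in the labels says that the replicates came from separate cultures. The p-values rest on counts of peaks or genes, random placements, random gene lists or permuted pairs of peaks. They do not measure spread between replicates.

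The first comparison asked whether both IPs placed RBM25 at the same positions. Of the 2696 peaks of replicate 1, 1645 overlapped a replicate 2 peak on the same strand (61.0%, 59.2 to 62.8), and these made up 20.3% of the longer list. In Srrt, which encodes a partner of the nuclear cap-binding complex, 16 of 17 replicate 1 peaks recurred, in the spliceosomal helicase gene Ddx46 10 of 10, and in Rbm25 itself 13 of 14. Among peaks assigned to genes, 1609 of 2590 were shared against a mean of 216 when replicate 2 peaks were placed at random within the span of the peaks of their gene, a 7.44-fold excess (one-sided permutation p = 0.001, the smallest that 1000 placements can give). When replicate 2 peaks were instead shuffled over the bins called for the gene in either list and on either strand, an alternative chosen after seeing the data, the expected number was 1560 and the excess 1.03-fold (permutation p = 0.0040); that pool holds the replicate 1 bins by construction, which raises the expected number. Placement anywhere on the chromosome gave a 2292-fold excess, a setting that ignores which genes were expressed. Neither this placement nor that within gene spans was matched on exon or intron. Of the 1200 sense peaks of replicate 1, 982 held coding sequence, so coverage that favours exons can raise the 7.44-fold excess.

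At the level of genes, 922 had a peak in replicate 1, 1819 in replicate 2 and 827 in both, and 652 genes held a peak shared by position. Chance overlap over the 47286 genes of the name table would be 33.0 genes, for 799 matched by name, and the odds ratio was 425. Over protein-coding genes alone, 774 genes stood against 62.9 and the odds ratio was 213. The two-sided Fisher exact p was too small for the software to represent with either background. Expression was not measured in these lists, so these ratios are upper values. With only the better part of each list by the authors' p-value, 472 genes had a peak in both lists and 345 held a shared peak.

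The strongest shared peak given for a gene is the shared peak with the most tags in replicate 1. The genes with the strongest shared peaks were led by Cald1, which encodes the actin-binding protein caldesmon. The strongest shared Cald1 peak lay in an intron at chromosome 4, 63297150 to 63297250 (mRatBN7.2, plus strand), with 120 tags in replicate 1 and 93.2 in replicate 2. An antisense peak overlapped it in each list, with 114.8 tags in replicate 1 and 89.6 in replicate 2. Next among named genes came Srrt, Akap8l, Ddx46, Luc7l3, Arglu1, Rbm25, Slc12a4, Sh3gl1 and Atn1. Luc7l3 encodes a U1 snRNP-associated protein and Arglu1 a splicing regulator. The strongest shared Arglu1 peak, on chromosome 16 at 80759600 to 80759650, had 59 and 103 tags, with a fraction of 0.18 of the bin in coding sequence and 0.82 in intron. An antisense replicate 2 peak in that bin had 125 tags and was not shared. Akap8l reached 62 and 123 tags at chromosome 7, 11347700 to 11347750, and Ddx46 64 and 84 tags at chromosome 17, 8982450 to 8982500; both peaks were antisense to their gene. Slc12a4, a potassium-chloride cotransporter gene, had 54 and 52 tags at its strongest shared peak, Sh3gl1 62 and 79, and Atn1 56 and 83. A further shared antisense peak of Slc12a4, at chromosome 19, 33860150 to 33860200, had 50 tags in replicate 1 and 110 in replicate 2. The strongest shared peaks of Srrt, Luc7l3, Rbm25, Slc12a4 and Sh3gl1 were also antisense.

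Rbm25 carried 14 peaks in replicate 1 and 18 in replicate 2 on chromosome 6. At 103311250 to 103311300, a bin spanning an exon-intron boundary, the sense peak had 32 tags in replicate 1 and 74 in replicate 2, and the antisense peak had 50 and 77. The tallest replicate 1 peak at this gene, antisense at 103304650 to 103304700, had 73 tags, and the replicate 2 peak that overlapped it had 24.5.

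**Figure D1:**
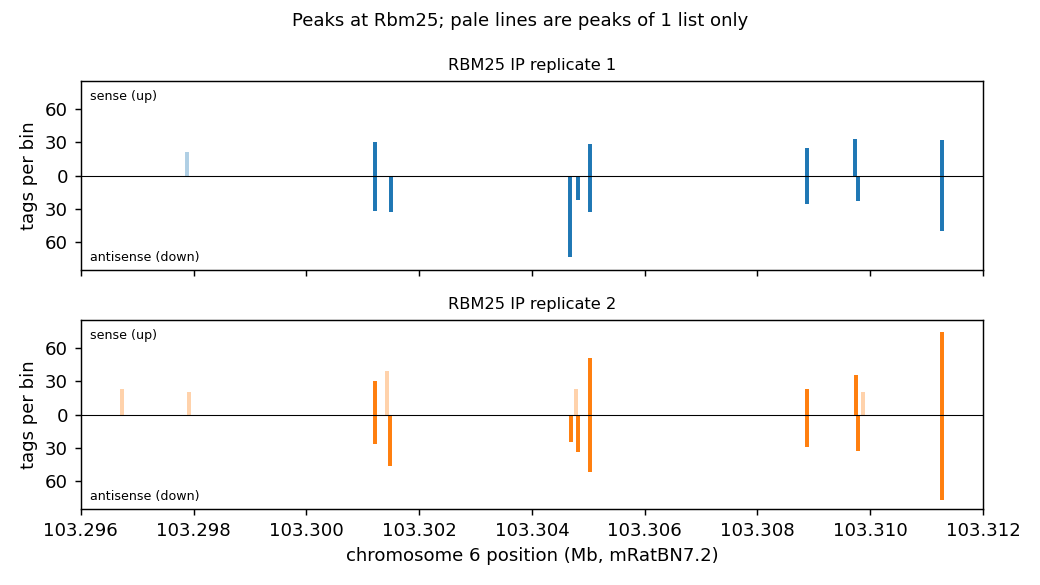
Peaks at Rbm25 on chromosome 6 (x axis, Mb, mRatBN7.2), with tags per bin on the y axis, sense peaks drawn upward and antisense peaks downward, replicate 1 above and replicate 2 below. Of the 14 replicate 1 peaks, 13 are dark, the mark of a peak shared with replicate 2.

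Across shared peaks, tag numbers in the lists were positively related. Spearman's rho across the 1645 pairs was 0.434 and Pearson's r 0.385 (permutation p = 1e-05 for each, the smallest that 100000 resamples can give); peaks are not independent replicates. Replicate 2 had more tags in 76.0% of pairs, with a median ratio of 1.24. Division of tags by peak length gave a rho of 0.339. Tags of longer peaks were already a mean over bins, so this setting corrects for length again and is a weak check.

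The next comparison asked where in genes the peaks lay, by the deposited annotation. Antisense positions took the most, 51.6% of peaks in replicate 1 (49.7 to 53.4) and 49.3% in replicate 2 (48.2 to 50.3). Coding sequence came next, with 24.2% and 29.2%, then introns, with 14.3% and 14.9%. The sizes rest on assigning a peak to the class that covers most of it: with coding sequence taken at any overlap, coding sequence was 40.4% of shared peaks in place of 26.4%, and introns 1.76% in place of 15.9%. The 5' UTR held 3.60% and 2.10%, noncoding exons 2.04% and 1.10%, intergenic sequence 3.93% and 2.80%, and the 3' UTR 0.371% and 0.678%. By two-sided Fisher exact test over peaks, the lists differed in coding sequence (adjusted p = 2.5e-06), 5' UTR (adjusted p = 8.9e-05), noncoding exons (adjusted p = 0.00098) and intergenic sequence (adjusted p = 0.0082). The antisense share did not pass that exact test (adjusted p = 0.052), nor did introns (adjusted p = 0.45) or the 3' UTR (adjusted p = 0.094). Ribosomal RNA loci, among them Rn45s and Rn28s, held 112 peaks and 14.5% of the tags in replicate 1 against 87 peaks and 2.36% of the tags in replicate 2 (share of peaks, Fisher exact adjusted p = 2.0e-20). Noncoding exon and intergenic peaks include peaks at these loci. Intergenic groups on scaffold_149 and scaffold_131 held 18 and 8 peaks in replicate 1, and 13 and 3 in replicate 2. The noncoding exon and intergenic differences were not tested without these loci, so they are not separate from the ribosomal RNA difference.

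**Figure D2:**
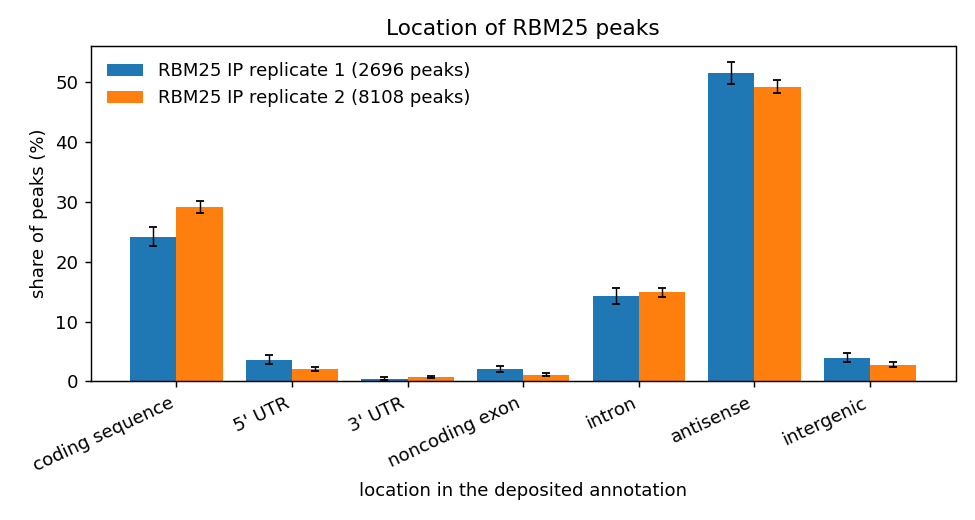
Share of peaks (y axis, %) by location in the deposited annotation (x axis) for each RBM25 IP list; error bars are 95% Wilson intervals. Antisense bars stand at 51.6% and 49.3%, and the 3' UTR bars are the lowest.

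Exon-intron boundaries ran through most sense peaks. In replicate 1, 814 of 1200 sense peaks held both exon and intron sequence (67.8%, 65.1 to 70.4), and in replicate 2 2767 of 3887 did (71.2%, 69.7 to 72.6). The share was higher in shared sense peaks, 76.6% against 51.8% of the remaining replicate 1 peaks (Fisher exact adjusted p = 7.6e-18) and 77.7% against 69.6% in replicate 2 (Fisher exact adjusted p = 5.8e-06). Luc7l2, which encodes another U1 snRNP-associated protein, had 5 boundary peaks in replicate 1 and 6 in replicate 2, Srrt 8 and 9, and the collagen gene Col16a1 13 and 22. In Ahnak, none of the 9 sense peaks of replicate 1 or the 19 of replicate 2 spanned a boundary. No random expectation for this share was computed, since exon positions of the build were not used here.

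Sense and antisense peaks often occupied the same bins. In replicate 1, 46.3% of plus-strand genic peaks had a minus-strand peak of the same list in a shared bin against 13.3% under random placement, and in replicate 2 67.7% did against 12.0% (one-sided permutation p = 0.001 in each list). Coro6 and Rbm25 showed such pairs, as did Foxo1, where replicate 2 had 3 intronic sense peaks and 3 antisense peaks in the same bins. Random placement was not matched on exon or intron, so coverage that favours exons can widen the excess in each list. In mirrored 51-nt pairs outside ribosomal RNA loci, the median antisense share of tags was 51.1% in each list. This covered 521 pairs in replicate 1 and 2383 in replicate 2. A pair was counted only where both strands were called, so bins with 1 strand below the lowest called tags drop out. A median near equal strands is thus partly set by the calls.

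Gene lists fixed before the data were examined were then compared. Splicing factor genes had the highest share of members with a shared peak among lists of at least 20 genes: 31 of 67 (46.3%, 34.9 to 58.1), against 1.77 in random lists of protein-coding genes. They included Rbm25, Luc7l3, Luc7l2, Pnn, Son, Srrm2, Srsf1, Hnrnpa1, Snrnp70 and U2af2. At their strongest shared peaks, Pnn had 55 tags in replicate 1 and 66 in replicate 2, and Luc7l2 53 and 27. The Luc7l2 peak was antisense, and another shared antisense Luc7l2 peak had 47 tags in replicate 1 and 45 in replicate 2. Of the 31 splicing factor genes, 30 had a shared sense peak, and Hnrnpa1 did not. Extracellular matrix and cytoskeleton genes followed with 15 of 52, sarcomere and muscle genes with 12 of 59 and cytosolic ribosomal protein genes with 12 of 77. Each of these lists exceeded random lists (two-sided permutation test, adjusted p = 0.00040 over lists; 0.0002 before adjustment is the smallest that 10000 lists can give). The ribosomal protein list did not pass with the better part of each peak list (4 genes, permutation adjusted p = 0.082), and against genes with a peak in either list neither it (permutation adjusted p = 0.30, with 12 genes below the mean of 16.5) nor the matrix list (permutation adjusted p = 0.098) passed. Random lists were not matched on expression or gene span, so genes without RNA in these cells count among them. The order after splicing factors holds for shared peaks only. By any peak in replicate 2, ribosomal protein genes (45 of 77, 58.4%) stood above matrix genes (27 of 52, 51.9%). By any peak in replicate 1, ribosomal protein genes (24.7%) stood just above muscle genes (23.7%).

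Among matrix and cytoskeleton genes, Ahnak had 43 and 23 tags at its strongest shared peak, the collagen chaperone gene Serpinh1 38 and 31, the laminin gene Lamc1 34 and 51, and Col16a1 34 and 27. Among muscle genes, Cald1 was followed by the tropomyosin gene Tpm3 with 52 and 50 tags, the nonmuscle myosin gene Myh10 with 33 and 37 and the filamin gene Flna with 36 and 21. Several of these muscle-list members, Myh10 and Flna among them, are also made in non-muscle cells. Rpl35 had 28 and 38 tags, Rpl13a 27 and 37, Rpl24 26 and 38 and Rps3a 29 and 30. Of these strongest shared peaks, those of Serpinh1, Col16a1, Tpm3, Flna, Rpl24 and Rps3a were antisense to their gene.

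Shared peaks were found in 7 of 49 apoptosis and stress genes (permutation adjusted p = 0.0019) and in 5 of 36 cell cycle genes (permutation adjusted p = 0.0080). With the better part of each peak list, 3 apoptosis and stress genes had a shared peak (permutation adjusted p = 0.10). So did 1 cell cycle gene (permutation adjusted p = 0.79), and neither list passed. With sense peaks alone, a setting chosen after seeing the data, 4 apoptosis and stress genes still passed (permutation adjusted p = 0.044). In that setting 2 cell cycle genes did not pass (permutation adjusted p = 0.38). The chaperone genes Hsp90aa1, Hspa5 and Hsp90ab1 had 37, 28 and 21 tags in replicate 1 at their strongest shared peaks, and 40, 29 and 38 in replicate 2, and the stress transcription factor gene Xbp1 had 29 and 38. Mcm2 had 25 and 31 tags, Top2a 23 and 32, Mcm4 24 and 24, and Bub1b 19 and 33. Of these peaks, those of Hsp90ab1, Xbp1, Mcm2, Top2a and Bub1b were antisense to their gene. Hsp90ab1, Xbp1, Mcm2 and Bub1b had no shared sense peak. With the random lists drawn only from genes with a peak in either list, splicing factors still exceeded them (permutation adjusted p = 0.0014), as did sarcomere and muscle genes (permutation adjusted p = 0.045). Under that background the apoptosis and cell cycle lists no longer passed (permutation adjusted p = 0.85 for each).

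Immune and inflammatory genes had no shared peak: 0 of 77 (upper limit of the interval, 4.75%), against 2.02 in random lists (permutation adjusted p = 0.30). Csf1, Hmgb1 and Tgfbr2 had a peak in each list at different positions, and 11 members, such as Stat3 and Il6st, had a peak in replicate 2, more than the 5.63 of random lists without passing (permutation adjusted p = 0.052). In replicate 1, 3 had a peak against 2.87. Against random lists of genes with a peak in either list, the count of 0 among 11 fell below the mean of 3.80 (permutation adjusted p = 0.045). In pairs of lists chosen after seeing the data, splicing factor genes exceeded ribosomal protein genes (two-sided Fisher exact adjusted p = 0.00023) and were not separated from matrix genes (Fisher exact adjusted p = 0.060).

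Of the 15 nuclear noncoding RNAs listed, 6 matched the name table by symbol or synonym. Among these, Rmrp matched only as a name of Rpph1, itself an entry, so it was not assessed as its own gene. Of the matched entries Gas5 had a peak, in replicate 2. Unmatched symbols can stand under other identifiers in the peak lists, so their lack of a peak was not assessed. Of 15 mitochondrially encoded genes, mt-Rnr2 and COX1 had a shared peak; mt-Rnr2 had 31 and 32 tags at positions 1100 to 1150 of the mitochondrial chromosome, and COX1 19 and 23 tags, antisense. Markers of other cell types had 1 gene of 20 with a shared peak, the smooth muscle gene Smtn (permutation adjusted p = 0.84). Its strongest shared peak had 41 and 55 tags and was antisense.

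**Figure D3:**
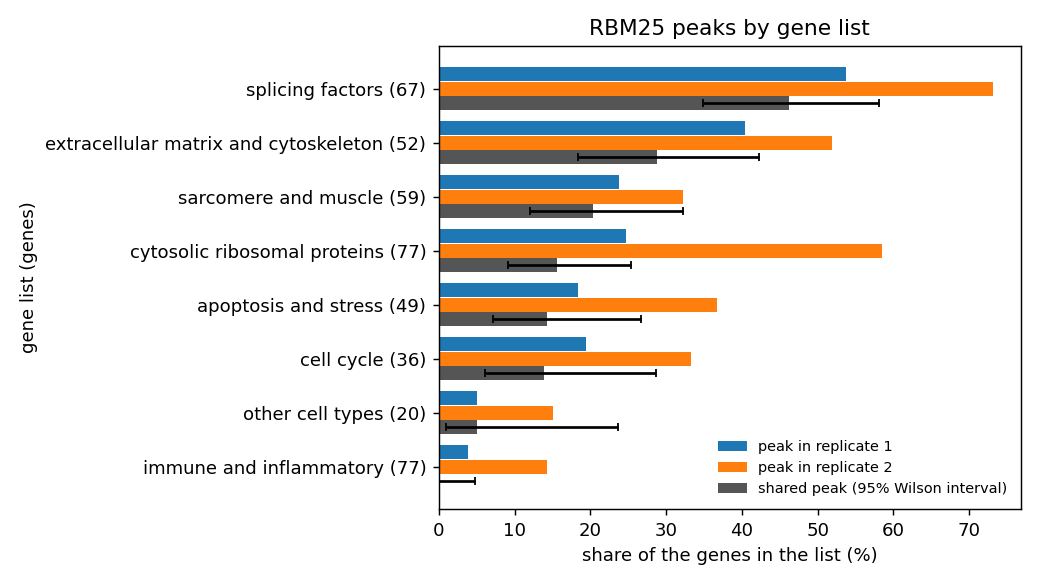
Share of the genes in each list (x axis, %) with a peak in RBM25 IP replicate 1, in replicate 2 and with a shared peak; the number of genes stands beside each list name (y axis) and error bars on the shared share are 95% Wilson intervals. Splicing factors lead with 46.3% and immune and inflammatory genes have 0.

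Genes that a study of RBM25 in these cells names were Slc38a9, Csf1 and Coro6; they are not independent evidence. Coro6, which encodes a coronin, had shared peaks on both strands at chromosome 10, 62318550 to 62318600, with a fraction of 0.84 of the sense bin in coding sequence and 0.16 in intron. The sense peak had 29 tags in replicate 1 and 38 in replicate 2, and the antisense peak 26 and 38. Csf1, the gene of a macrophage growth factor, had an antisense peak in each list on chromosome 2, at 195388750 to 195388800 with 25 tags in replicate 1 and at 195384450 to 195384500 with 23 tags in replicate 2, with no overlap. Slc38a9 had no peak in either list.

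The known RBM25 targets Bin1 and Bcl2l1 had no shared peak. Bin1 had 1 peak in replicate 1 and 3 in replicate 2. Bcl2l1 had peaks in replicate 2 alone, on both strands at chromosome 3, 141302550 to 141302600, with 20 tags on the sense strand and 27 on the antisense strand.

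Some strong peaks lay in genes with no peak in the other list. In replicate 1 these were led by Rplp1 (119 tags, antisense), the histone gene H2ac20 (108 tags, coding sequence) and Mphosph9 (up to 52 tags, antisense). In replicate 2 they were led by Anp32b (up to 154 tags), the transcription factor gene Foxo1 (up to 138) and Dym (up to 137). Recurrence was compared between classes of strength chosen after seeing the data. Outside ribosomal RNA loci, 71.6% of replicate 1 peaks of over 24 to 40 tags were shared and 51.1% of the 45 peaks of over 60 tags (two-sided Fisher exact p = 0.0065). In replicate 2 the same classes did not differ by that test, with 25.5% and 26.2% shared (Fisher exact p = 0.80).

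**Figure D4:**
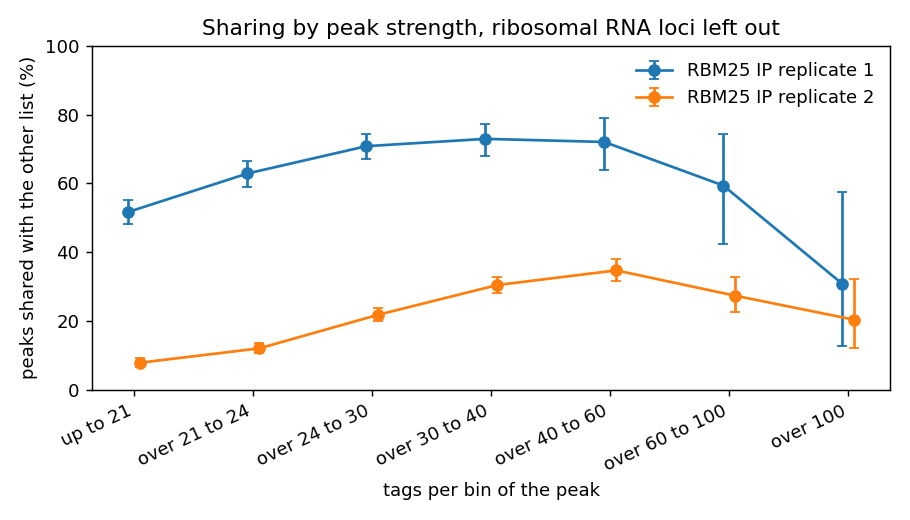
Share of peaks that overlap a peak of the other list on the same strand (y axis, %) by tags per bin (x axis) for each RBM25 IP list, with ribosomal RNA loci left out; error bars are 95% Wilson intervals. In replicate 1 the share is 51.7% at up to 21 tags, 73.0% at over 30 to 40 and 30.8% above 100, where 13 peaks remain.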

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

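Shuffling over called bins, sense peaks alone, and location without mitochondrial, scaffold and ribosomal RNA peaks were chosen after seeing the data; other settings were planned. No paired analysis was possible because no input values were used, and the replicate numbers of the IPs pair no groups. The excess of shared peaks over random placement stayed past its threshold in all settings run, and its size ranged from 1.03-fold over called bins, a pool that holds the replicate 1 bins by construction, to 2292-fold over chromosomes. With the better part of each list by p-value, antisense peaks were 53.6% of shared peaks, coding sequence 22.2% and boundary peaks 80.1% of sense peaks, 472 genes had a peak in both lists and 345 a shared peak; fewer peaks entered. That setting left 4 ribosomal protein genes, 3 apoptosis and stress genes and 1 cell cycle gene, none of these lists past the threshold. Against genes with a peak in either list, 15 matrix, 7 apoptosis and 5 cell cycle genes no longer passed, the 12 ribosomal protein genes turned to below the mean, and the 0 immune genes passed as a deficit; the cause was not tested. With sense peaks alone, 2 cell cycle genes had a shared peak and the list no longer passed. Location by any overlap gave 40.4% coding sequence and 1.76% intron, by construction. Without replicate 1 or replicate 2, coding sequence ranged from 24.2% to 29.2% and boundary peaks from 67.8% to 71.2%. Of the other values, 69 stayed on their side. For named genes, 75 counts of shared peaks stayed within 1.5 times and 17 did not. All 17 came with the better part of each list by p-value. The 75 include genes with no shared peak in the main setting, such as Slc38a9 and Foxo1, which a stricter rule leaves at 0 by construction. Exon- and intron-matched placement, windows of other widths around splice sites, lists matched on exonic length and all motif settings were not run. Unknown depth limits any reading of list length.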

Other observations

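All tests in this part were chosen after the results were seen. A group of peaks was seen in replicate 2 alone: 16 peaks on chromosome 9, 13 of them intergenic and 3 in LOC120094650, reached 453.5 tags, and replicate 1 had none there. The strongest replicate 2 peak, 651 tags antisense to Col1a1 on chromosome 10 at 79896450 to 79896500, was not shared either.

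Mirrored sense and antisense peaks could arise if the strand of fragments was not kept. In that case about 95% of mirrored bins with at least 80 tags would lie in the binomial 95% range around equal strands. In replicate 2 93.2% did (90.5 to 95.3), near that share, and in replicate 1 85.7% of 42 bins did (72.2 to 93.3), which leaves replicate 1 open. Only bins called on both strands entered, so strong bins with 1 strand uncalled drop out. These shares are thus partly set by the calls. Loss of strand also predicts that nearly all peaks of at least 40 tags have a peak on the other strand within 200 nt. Among antisense peaks 68.7% of 115 in replicate 1 had one (59.7 to 76.5) and 91.7% in replicate 2 (89.3 to 93.6), and among sense peaks 75.7% (64.5 to 84.2) and 86.2% (83.3 to 88.7). Except for the antisense peaks of replicate 2, these shares lie below 90% by more than their intervals. The prediction assumes that tags are separate fragments and that each bin with enough tags was called. The caller and its filters are unknown and duplicated fragments were not tested. The shares therefore leave loss of strand open, for mirrored peaks and for peaks without a partner, such as the Rplp1 peak. Antisense transcription and DNA in the libraries were not tested, and neither was a biological explanation, since the inputs were not used here.

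Among 51-nt coding boundary peaks, 42.9% in replicate 1 and 39.2% in replicate 2 had less than a fraction of 0.5 in coding sequence. Spearman's rho between coding share and tags across these peaks was 0.035 and 0.010 (permutation p = 0.34 and 0.62); all had already been called on their tags, so no explanation was tested.

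The lower recurrence of the strongest replicate 1 peaks might reflect ribosomal RNA, which held 14.5% of replicate 1 tags. With those loci left out, 51.1% of replicate 1 peaks of over 60 tags were shared against 71.6% of those of over 24 to 40 tags (Fisher exact p = 0.0065), which argues against ribosomal RNA as the whole cause. In replicate 2, peaks of over 60 tags were shared at 26.2% against 25.5% for over 24 to 40 tags (Fisher exact p = 0.80) and 34.7% for over 40 to 60 (Fisher exact p = 0.0039), so a lower share there depends on the class compared. Duplicated fragments and a biological difference between the samples were not tested.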
